A study of Mus musculus with 8 samples.

How the data were processed

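RNA from epididymal white adipose tissue, the fat pad beside the testis of the mouse, was measured on Affymetrix 3′ expression arrays, 1 array per animal. The labels give 4 LPA4-KO mice (male carriers of a deficient Lpar4 allele on their X chromosome) and 4 wild-type (WT) mice, all male littermates of the C57BL/6 background aged 12 weeks. Per the labels' protocols, the tissue was frozen in liquid nitrogen, total RNA was prepared with a kit for lipid-rich tissue, and biotin-labelled RNA was made with a 3′ in vitro transcription kit. Samples were placed in groups by the genotype in the labels and named by the replicate numbers given there, which the labels describe as biological replicates.

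The deposited values are 1 number per probe set and array and were used as log2 values. R 2.14.0 is the software named in the submitters' processing notes. The background correction, the normalization, the summarisation of probes and the base of the logarithm are not given in the sources used here. The log2 scale was inferred from the values, which ran from 5.27 to 14.07 with array medians between 6.50 and 6.51. A fold in the text therefore rests on that reading. The value table matched all 8 samples by name.

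Of 45101 probe sets, 37501 (83.1%) spanned no more than 0.1 log2 between the lowest and the highest array, with a median range of 0.00052 log2. The other 7600 had a median range of 0.53 log2. Probe sets with signals at the top of the scale were among the nearly constant ones, so a flat value here cannot be read as a measured lack of change. Genes were called varying if their probe set spanned over 0.1 log2, a limit that was set after the values were seen. The depth of an array cannot be stated as a count, and the number of arrays limits the precision.

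Probe sets were named from the platform annotation given with the data. It listed 34945 probe sets with 1 gene symbol and 932 with several, 9160 probe sets had no listed gene, and 64 were controls. Through the Entrez number, 34741 of the named probe sets matched a gene in the mouse RefSeq table of assembly GRCm38.p6, and 0 symbols changed. Probe sets with no gene or several genes were left out of the gene comparisons. Each of the 18193 genes was represented by its probe set with the highest mean over all 8 arrays, and 4029 of these genes varied. Genes with no probe set of their own in the annotation were not analysed here. No genome build is given in the sources used here, so the RefSeq table served only for names and for the order of genes around Lpar4.

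Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on level), with no filter on level and no block. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called, and every adjusted p of a gene in the text comes from limma. Lpar4 was tested in a fit of all named probe sets and with an exact two-sided permutation test over the 70 arrangements of 4 arrays against 4, whose smallest possible p is 0.0286. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 54 lists with at least 3 measured members. Camera compares a list with all other genes. The lists were also tested with camera using an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. RNA and array quality were compared by the 3′ to 5′ difference of the Gapdh and Actb control probe sets, the array medians and interquartile ranges, and correlations between arrays, each with an exact permutation test.

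These designs, the 54 lists and the rule for named genes were fixed before the data were examined. The rule names Lpar4, the 10 largest rises and the 10 largest falls among called genes with a proper name (2010106E10Rik was passed over), and, for each list described, the 2 members with the smallest p, the 2 with the highest level and all called members. It adds members of the list of genes near Lpar4 with an unadjusted p under 0.05. Alternatives fixed at the same time were a filter on genes above the median level, quantile normalization, median centring, eBayes without a trend or with robust estimation, array weights, the replicate number as a block, each array left out in turn, the mean of all probe sets per gene, every probe set on its own, a plain equal-variance test, and other thresholds. A fit restricted to the varying genes, with and without a second scaling, was added after seeing the data.

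The steps were tested on simulated data with the residual spread of these arrays. All changed genes were drawn from the 4029 varying genes, so the shares recovered do not hold for nearly constant genes. Of 100 simulated genes changed 1.5-fold the fit of all 18193 genes recovered 48%, and of 100 changed 2-fold it recovered 73%, with 10 false calls among 131. With the 4029 varying genes only, 76% and 95% were recovered, with 9 false calls among 180. A simulated shift of 0.3 log2 in 17 genes of the tricarboxylic acid cycle list was called by camera, and no other list was. Each simulated gene was drawn independently, so the simulation does not test false list calls among correlated genes. In the real arrays the estimated correlation was 0.13 for that list and 0.87 for a list of mesothelial markers.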

Results

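Gene expression was measured in epididymal white adipose tissue of male mice that lacked LPA4, a G protein-coupled receptor for lysophosphatidic acid encoded by the X-linked gene Lpar4, and of wild-type littermates. The comparison asked which genes differ in this fat depot when the receptor is deficient. There were 4 LPA4-KO and 4 WT arrays, each from a separate mouse of 12 weeks. All values are on the log2 scale of the deposited table, errors of group means are SD with n = 4, and errors of log2 fold changes (LPA4-KO minus WT) are SE. Most genes were nearly constant in this table. Of 18193 genes, 14164 (77.9%) spanned no more than 0.1 log2 over the 8 arrays and 4029 varied.

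**Figure D1:**
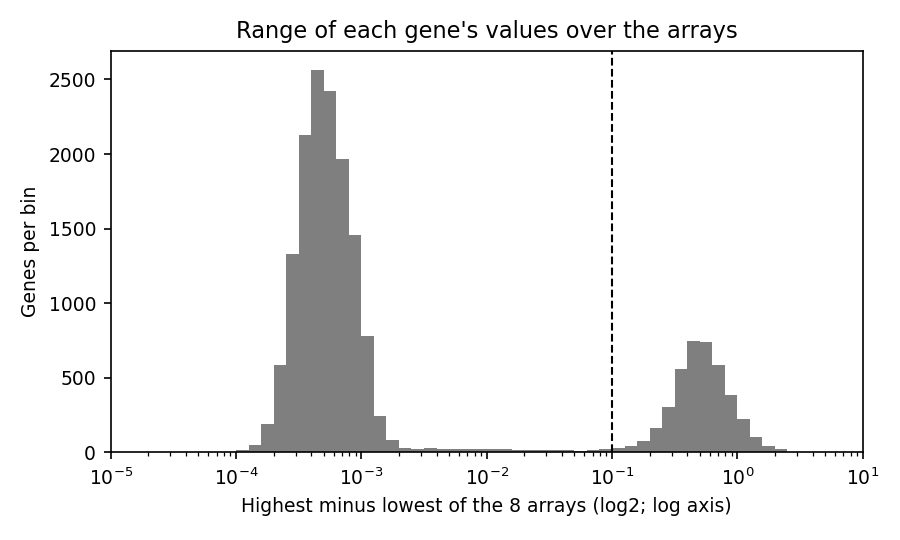
Number of genes (vertical axis) by the difference between the highest and the lowest of the 8 arrays in log2 (horizontal axis, logarithmic). The dashed line at 0.1 log2 separates the 4029 varying genes on its right from the 14164 nearly constant genes on its left.

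The targeted gene was lower in all 4 LPA4-KO arrays at 1 of its 3 probe sets and not at the others. At probe set 1452424_at, Lpar4 stood at 5.80 ± 0.05 in LPA4-KO and 6.52 ± 0.03 in WT mice, a 1.64-fold lower level (log2 fold change -0.71 ± 0.03, adjusted p = 0.0033). Its WT mean lay above only 44.4% of named probe sets. Signal above background was not tested, so the fold is not a measure of the Lpar4 RNA that remains. The highest LPA4-KO array was at 5.86 and the lowest WT array at 6.48, and the exact permutation p was 0.0286, the smallest possible with 4 against 4 arrays. At 1434186_at the means were 7.11 ± 0.46 and 6.43 ± 0.18 (log2 fold change 0.68 ± 0.24, adjusted p = 0.23, exact permutation p = 0.057). The third, 1439665_at, had the highest mean, with 7.35 ± 0.51 against 6.87 ± 0.09 (0.48 ± 0.25, adjusted p = 0.39, exact permutation p = 0.143). The part of Lpar4 that was deleted and the place of each probe set relative to it are not given in the sources used here, so only the first probe set separated the genotypes as labelled, and a probe set outside the deleted part would check nothing.

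**Figure D2:**
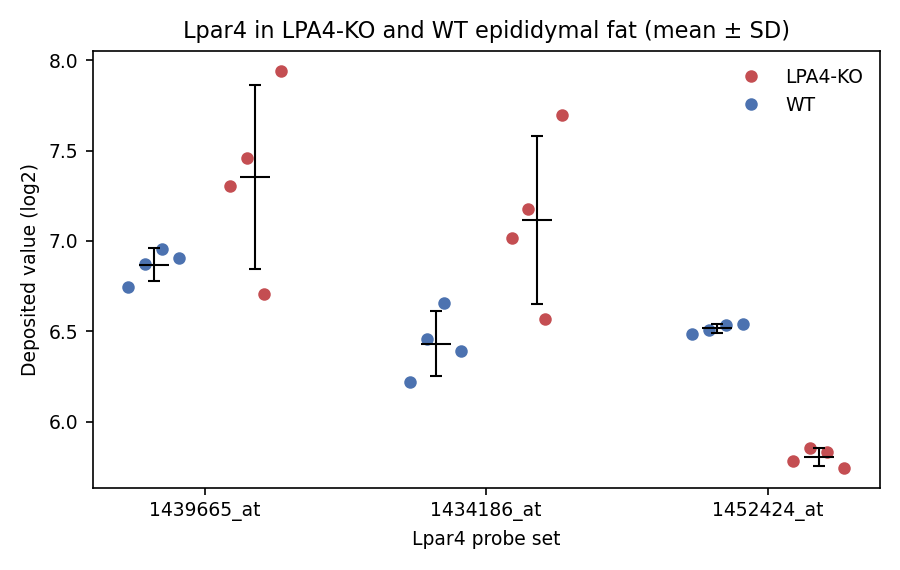
Deposited log2 values (vertical axis) of the 3 Lpar4 probe sets (horizontal axis) in the 4 LPA4-KO arrays (red) and the 4 WT arrays (blue), with mean and SD in black. At 1452424_at all LPA4-KO arrays lie at or below 5.86 and all WT arrays at or above 6.48, while the groups overlap at the other probe sets.

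Among the largest changes, single genes of lipid, pyruvate and coenzyme A metabolism were higher in LPA4-KO fat, and single genes of the extracellular matrix and of the contractile apparatus were lower. Cyp2f2, a cytochrome P450, had the largest rise, from 7.36 ± 0.34 in WT to 9.79 ± 0.30 in LPA4-KO mice (5.41-fold, log2 fold change 2.44 ± 0.22, adjusted p = 0.021). Pcx, the pyruvate carboxylase that makes oxaloacetate from pyruvate, rose 1.73-fold (0.79 ± 0.09, adjusted p = 0.029). Coasy, the enzyme of the last steps of coenzyme A synthesis, rose 1.57-fold, Hsd17b12, an enzyme of fatty acid elongation, 1.53-fold, and the carboxylesterase gene Ces1f 2.02-fold. The chaperone gene Hsph1 rose 1.93-fold. The remaining largest rises were Nabp1 (2.23-fold), which encodes a protein that binds single-stranded DNA, Cks1b (1.75-fold), which encodes a subunit of cyclin-dependent kinases, Nmb (1.65-fold), the gene of the peptide neuromedin B, and Tmtc4 (1.57-fold). Adjusted p for these 10 genes ran from 0.021 for Cyp2f2 to 0.0498 for Cks1b.

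Thbs2, which encodes the matrix protein thrombospondin 2, fell from 10.33 ± 0.10 to 8.83 ± 0.30 (2.82-fold lower, log2 fold change -1.50 ± 0.15, adjusted p = 0.023). Lox, the lysyl oxidase that cross-links collagen and elastin, was 2.49-fold lower (-1.32 ± 0.16, adjusted p = 0.030), and the elastic fibre gene Fbln5 was 1.92-fold lower (-0.94 ± 0.08, adjusted p = 0.017). Fibronectin, Fn1, was 1.84-fold lower. Acta2, the smooth muscle actin also made by contractile fibroblasts, was 2.48-fold lower (-1.31 ± 0.21, adjusted p = 0.0498), and Synpo2, which encodes an actin-binding protein, 2.47-fold lower. The list of falls closed with Rasl11b (2.03-fold lower), the ficolin gene Fcna (1.85-fold), the transcription factor gene Klf10 (1.80-fold) and Fam20a (1.73-fold). In each of these 20 genes the groups did not overlap. The genes were chosen as called genes with the largest changes in the same arrays, so this separation is not further evidence.

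**Figure D3:**
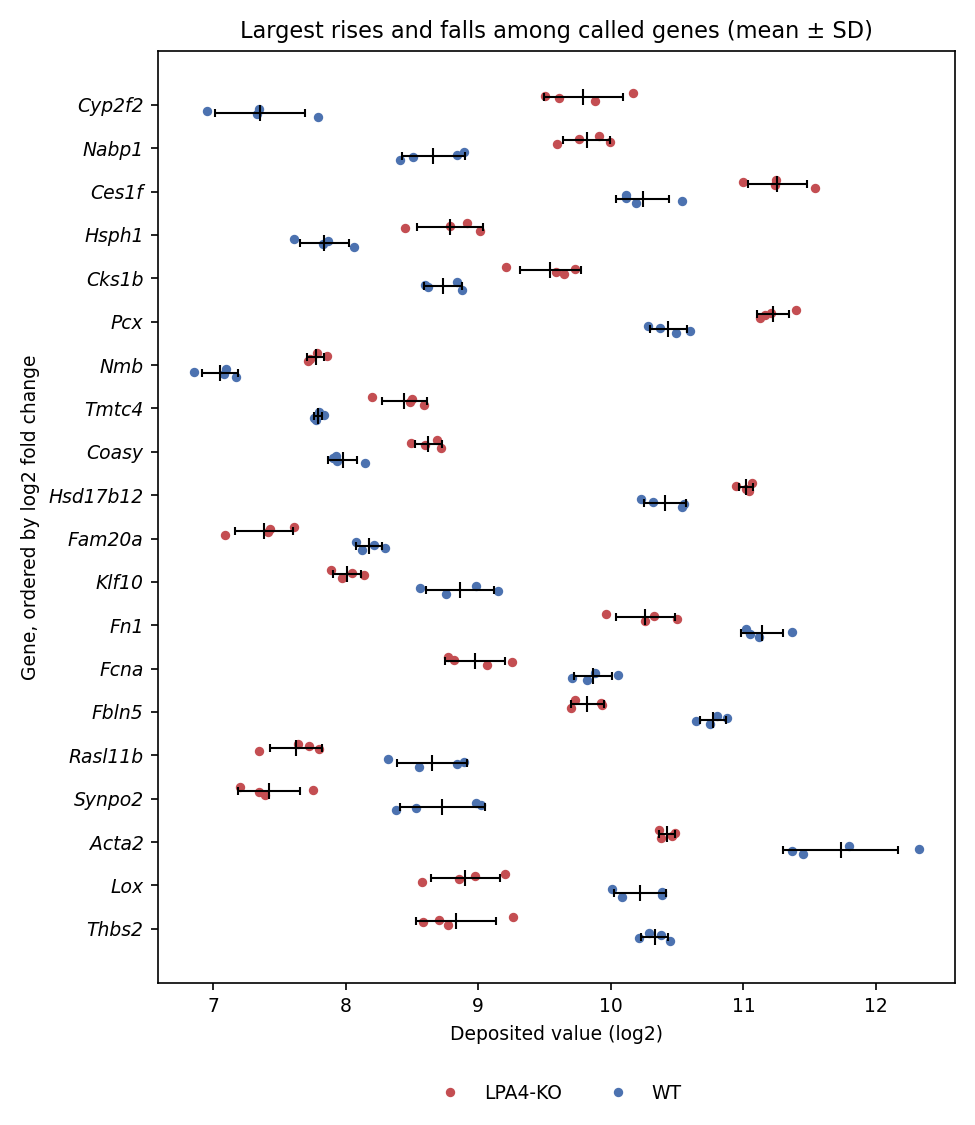
Deposited log2 values (horizontal axis) in the 4 LPA4-KO arrays (red) and the 4 WT arrays (blue) for the 10 largest rises and 10 largest falls among called genes (vertical axis, ordered by log2 fold change), with mean and SD in black. The groups are apart in every gene, from Cyp2f2 (log2 fold change 2.44) at the top to Thbs2 (-1.50) at the bottom.

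In total 239 of 18193 genes were called, 157 higher and 82 lower in LPA4-KO mice, and 27 of them (12 higher, 15 lower) differed at least 1.5-fold. Of the 239, 190 varied (124 higher, 66 lower), and 49 were nearly constant genes whose differences were at most 0.011 log2. The median size of change in the called varying genes was 0.37 log2. When the varying genes were fitted alone, a choice made after seeing the data, 859 of 4029 were called, 394 higher and 465 lower, among them 179 of the 190, and 124 differed at least 1.5-fold (36 higher, 88 lower). The groups did not overlap in 1163 varying genes (28.9%), where chance gives 2.86%. Each array mattered to the count over all genes, which was 26, 25, 9 and 32 without LPA4-KO replicate 1, 2, 3 or 4 and 88, 22, 30 and 18 without WT replicate 1, 2, 3 or 4. With 1 array left out the 44 called genes named in the text kept their direction in all 352 results and their call in 41. In the varying genes alone the matching counts of called genes were 450, 523, 540, 536, 847, 668, 405 and 556. The share of higher genes depended on scaling: after quantile normalization 8799 genes were called higher and 637 lower, and after median centring 14152 and 758, since a common shift of nearly constant values passes the test. In the varying genes alone those scalings gave 502 higher and 376 lower, and 477 higher and 403 lower.

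Genes of mitochondrial energy metabolism were higher in LPA4-KO fat, by small amounts. In the 8 lists of this kind, 217 genes were measured and 128 varied, 121 of them with a positive difference. Over all genes tested 17 of the 217 rose and 0 fell, and in the varying genes alone 47 rose and 0 fell. Camera called all 8 lists higher at the preset correlation, and none with an estimated correlation (adjusted p from 0.22 to 0.52). After quantile normalization over all genes camera kept the call of the tricarboxylic acid cycle list alone and turned ATP synthase and the mitochondrial ribosome to lower without a call. Median centring ended all 8 calls and turned complex IV, ATP synthase and fatty acid oxidation. Within the varying genes all 8 calls held under both scalings. In the tricarboxylic acid cycle list 4 of 20 members rose (14 adjusted over the list alone), with a median over varying members of 0.24 log2 and an adjusted p of 5.65e-09. Its estimated-correlation test gave adjusted p = 0.22. Besides Pcx, these were Dlat (0.56 ± 0.04) and Dld (0.32 ± 0.03), parts of the pyruvate dehydrogenase complex, and Idh3a (0.34 ± 0.05), a subunit of isocitrate dehydrogenase. Mdh2 and Pdha1 differed by 0.21 ± 0.04 and 0.09 ± 0.05 and did not pass.

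In the respiratory chain, all 23 varying members of the complex I list were positive, and 3 of 35 measured rose (9 adjusted over the list alone): Ndufs1 (0.30 ± 0.04), Ndufa5 (0.29 ± 0.04) and Ndufv2 (0.23 ± 0.03). The adjusted p of the list was 5.54e-06, and adjusted p = 0.31 with an estimated correlation. All 14 members of the list of complexes II and III, which includes cytochrome c, were positive, and Cycs (0.52 ± 0.08) and Cyc1 (0.37 ± 0.04) rose (10 adjusted over the list alone; list adjusted p = 4.01e-07, and adjusted p = 0.22 with an estimated correlation). In the ATP synthase list 1 of 16 rose, Atp5g3 (0.23 ± 0.03), and 5 adjusted over the list alone (list adjusted p = 0.0041, and adjusted p = 0.45 with an estimated correlation). No member of the complex IV list passed over all genes and 1 of 12 did adjusted over the list alone. Cox5a differed by 0.24 ± 0.05 (list adjusted p = 0.027, and adjusted p = 0.52 with an estimated correlation). The complex IV call also ended among genes above the median level, with array weights and without LPA4-KO replicate 4.

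Of 31 genes of mitochondrial import and biogenesis, 4 rose (8 adjusted over the list alone): Polrmt (0.26 ± 0.02), the mitochondrial RNA polymerase, Phb2 (0.29 ± 0.03), Timm50 (0.32 ± 0.05) and the mitochondrial chaperone gene Hspd1 (0.28 ± 0.03). The list had an adjusted p of 8.41e-06, and adjusted p = 0.28 with an estimated correlation. None of 73 mitochondrial ribosome genes passed over all genes and 2 did adjusted over the list alone, with 19 of 21 varying members positive (list adjusted p = 3.37e-05, and adjusted p = 0.28 with an estimated correlation). In mitochondrial fatty acid oxidation 3 of 18 rose, Slc25a20 (0.31 ± 0.03), the carnitine-acylcarnitine carrier, Etfdh (0.35 ± 0.04) and Etfb (0.23 ± 0.03), while adjusted over the list alone 8 rose and 1 fell. Hadh (0.05 ± 0.08) and Acadm (0.16 ± 0.06) did not pass. This list had an adjusted p of 3.37e-05, and adjusted p = 0.22 with an estimated correlation.

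The lists of fatty acid synthesis and of triglyceride synthesis and lipid droplets were called higher as well, while cholesterol synthesis was not called (adjusted p = 0.72), with 3 varying members positive and 4 negative. Both calls ended under either scaling over all genes, where triglyceride synthesis turned to lower, and held within the varying genes. All 11 varying members of the fatty acid synthesis list were positive, with a median of 0.39 log2, and Slc25a1, the citrate carrier, rose (0.36 ± 0.06), with 5 of 17 passing adjusted over the list alone (list adjusted p = 0.0026, and adjusted p = 0.27 with an estimated correlation). Me1, the cytosolic malic enzyme, differed by 0.31 ± 0.05 with an adjusted p of 0.058. In triglyceride synthesis and lipid droplets, Dgat1 (0.46 ± 0.07), which makes triglyceride from diacylglycerol, and Bscl2 (0.45 ± 0.05), the seipin gene, rose, 2 of 19 members in all and 4 adjusted over the list alone (list adjusted p = 0.0077, and adjusted p = 0.31 with an estimated correlation). Pck1 differed by -0.18 ± 0.10 and did not pass. In branched-chain amino acid breakdown 13 of 14 varying members were positive and no member passed over all genes; adjusted over the list alone 1 did, and Mccc1 had the smallest p (0.46 ± 0.08). That list had an adjusted p of 0.0023, and adjusted p = 0.41 with an estimated correlation, and its call ended under either scaling over all genes, with the direction turned by centring.

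The heat shock, proteasome and endoplasmic reticulum stress lists were called higher by camera. Over all genes quantile normalization kept the heat shock call alone, median centring ended all 3, and both turned the proteasome and endoplasmic reticulum stress lists to lower. All 9 varying heat shock genes were positive, with a median of 0.39 log2, and 3 of 11 rose: Hsph1, Dnaja1 (0.54 ± 0.06) and Hspd1 (8 adjusted over the list alone). Hsp90aa1 (0.22 ± 0.11) and Hspa8 (0.11 ± 0.03) did not pass over all genes. The list had an adjusted p of 5.17e-06, and adjusted p = 0.28 with an estimated correlation. In the proteasome list 1 of 39 rose, Psmd1 (0.36 ± 0.05), and 10 adjusted over the list alone (list adjusted p = 0.00014, and adjusted p = 0.22 with an estimated correlation). In endoplasmic reticulum stress 1 of 21 rose, Dnajb9 (0.51 ± 0.07), and 2 adjusted over the list alone, while Hspa5 differed by 0.18 ± 0.08 (list adjusted p = 0.020, and adjusted p = 0.31 with an estimated correlation). The call of this list ended without LPA4-KO replicate 2 and without WT replicate 4. The list of cytosolic ribosomal proteins was called lower, and lost its call in the varying genes after quantile normalization (adjusted p = 0.11). None of 49 passed over all genes or adjusted over the list alone, and 15 of 17 varying members were negative with a median of -0.09 log2 (list adjusted p = 0.00014, and adjusted p = 0.38 with an estimated correlation).

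**Figure D4:**
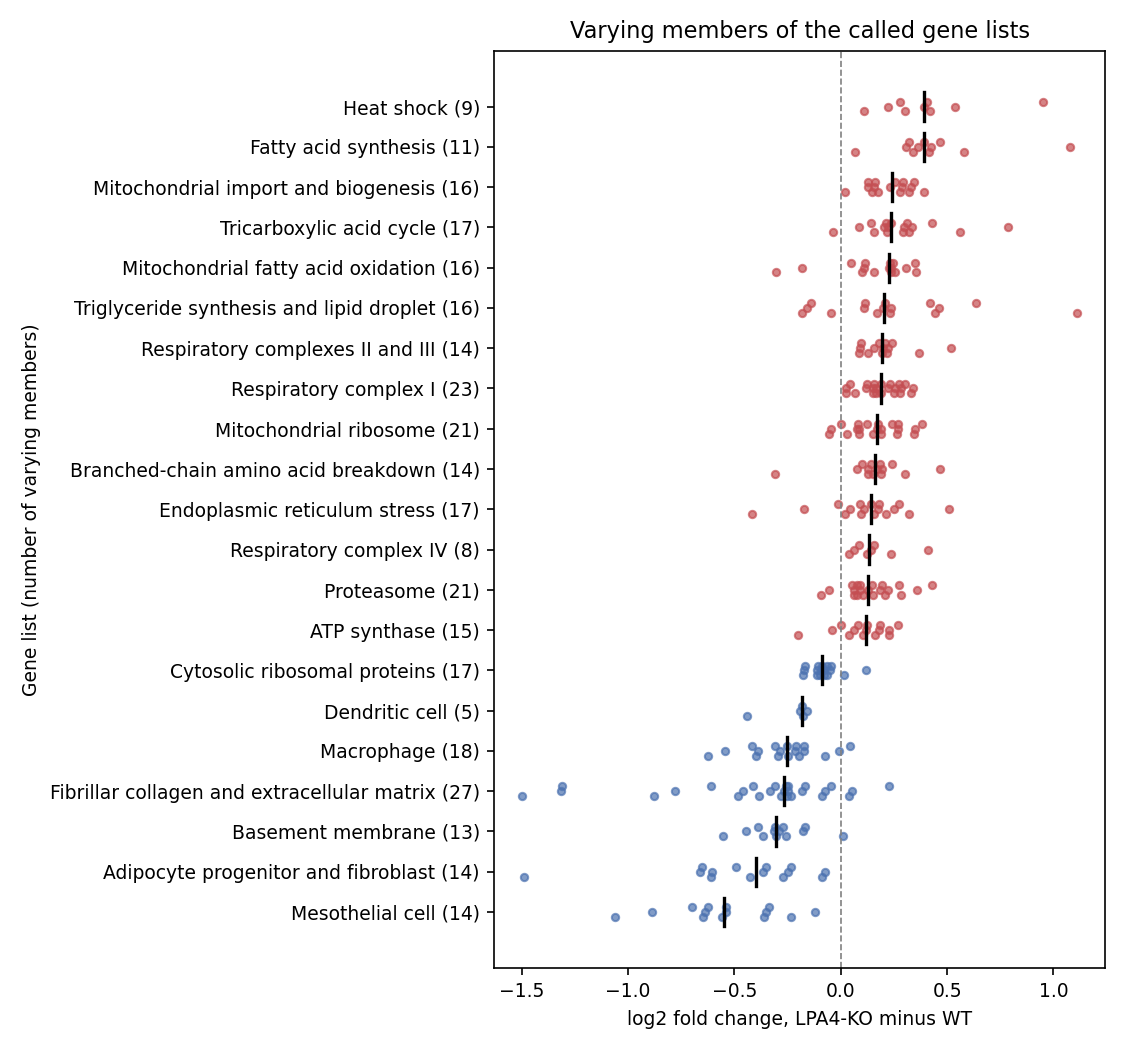
Each point is the log2 fold change (horizontal axis, LPA4-KO minus WT) of 1 varying member of a gene list (vertical axis, number of varying members in brackets), for the 21 called lists with at least 3 varying members. Red lists were called higher and blue lists lower, and the black bar is the median, from 0.39 for heat shock genes to -0.55 for mesothelial genes.

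Extracellular matrix genes were lower in LPA4-KO fat. Of 30 measured genes of fibrillar collagen and matrix 4 fell over all genes, Thbs2, Lox, Fn1 and Acta2, and 11 adjusted over the list alone, with 24 of 27 varying members negative. Acta2 encodes an actin and stands in this list as a marker of matrix-producing contractile cells. Dcn (-0.25 ± 0.09) and Sparc (-0.31 ± 0.09) did not pass. The list had an adjusted p of 1.92e-07, and adjusted p = 0.31 with an estimated correlation. In the basement membrane list 1 of 14 fell, the laminin gene Lamc1 (-0.29 ± 0.05), and 9 adjusted over the list alone, with 12 of 13 varying members negative. Lama2 (-0.45 ± 0.08), Nid1 (-0.31 ± 0.08) and Col4a1 (-0.30 ± 0.10) did not pass over all genes. This list had an adjusted p of 5.87e-08, and adjusted p = 0.27 with an estimated correlation.

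Camera called lists of markers of progenitors and fibroblasts, mesothelial cells, macrophages and dendritic cells lower at the preset correlation, and none of these with an estimated correlation (adjusted p from 0.28 to 0.41). With fry, which tests whether members move one way on balance, the progenitor list kept its call (adjusted p = 0.023), and the mesothelial (adjusted p = 0.15), macrophage (adjusted p = 0.056) and dendritic cell (adjusted p = 0.11) lists did not. All 14 varying markers of adipocyte progenitors and fibroblasts, 4 of whose genes also stand in the matrix list, were negative. Of 18 measured, Dpt, the dermatopontin gene, fell by 0.43 on the log2 scale (SE 0.04), and 7 fell adjusted over the list alone. The list had an adjusted p of 8.22e-06, and adjusted p = 0.28 with an estimated correlation. Ccn5 had a larger difference with more spread (-1.49 ± 0.26, adjusted p = 0.059). All 14 varying mesothelial markers, genes of the sheet of cells that covers the pad, were negative with a median of -0.55, and none of 15 passed over all genes or adjusted over the list alone, while in the varying genes alone 4 fell, and 7 adjusted over the list alone. Gpm6a differed by -1.06 ± 0.29 and Upk3b by -0.62 ± 0.22. This list had an adjusted p of 5.88e-06, and adjusted p = 0.41 with an estimated correlation. That correlation was 0.87, so the markers moved together and are not separate pieces of evidence. The mean over varying markers overlapped between groups, with WT replicate 4 at 7.87 below LPA4-KO replicate 2 at 8.03 (exact permutation p = 0.086). Among macrophage markers 17 of 18 varying members were negative and none of 24 passed over all genes, while 6 fell adjusted over the list alone and 6 in the varying genes alone (list adjusted p = 1.43e-05, and adjusted p = 0.31 with an estimated correlation). Lyz2 differed by -0.42 ± 0.09, Retnla by -0.54 ± 0.11 and Mpeg1 by -0.31 ± 0.05. The dendritic cell list was called lower too (adjusted p = 0.029, and adjusted p = 0.31 with an estimated correlation). Of its members 0 of 13 passed the threshold over all genes and 1 was lower in the varying genes alone. Its call ended under either scaling, with the mean of all probe sets per gene, and without LPA4-KO replicate 3 or 4 or WT replicate 3. Camera within the varying genes did not call it (adjusted p = 0.18).

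Camera called no list of markers of the adipocyte itself or of vessels. Of 15 adipocyte identity and adipokine genes none passed over all genes or adjusted over the list alone, and the median over 11 varying members was 0.12 log2 (list adjusted p = 0.66). Adipoq and Car3 of this list and Fabp4 and Scd1 in other lists were nearly constant, at most 0.00022 log2 apart between groups, and carry no information on change. Retn differed by 0.18 ± 0.06 (adjusted p = 0.18). In the smooth muscle and pericyte list Acta2 fell while Actg2, the enteric actin, was higher by 0.74 ± 0.15 without passing (adjusted p = 0.072), and the list was not called (adjusted p = 0.58). The blood endothelial list missed the threshold of camera (adjusted p = 0.078), as did lipolysis (adjusted p = 0.70), insulin signalling (adjusted p = 0.81), glycolysis (adjusted p = 0.18), inflammatory cytokines (adjusted p = 0.14), brown and beige genes (adjusted p = 0.080) and immediate early genes (adjusted p = 0.70). Among these, fry called the blood endothelial list lower (adjusted p = 0.019), and glycolysis (adjusted p = 0.032) and brown and beige genes (adjusted p = 0.029) higher. Camera within the varying genes called none of these (adjusted p from 0.18 to 0.42). Only 5 of 19 brown and beige genes varied, and none passed over all genes, adjusted over the list alone or in the varying genes. Fry also called the T and NK cell list (adjusted p = 0.018), whose members were all nearly constant, so such genes can carry its call. Slc2a4, the insulin-responsive glucose transporter, differed by 0.70 ± 0.20 with an adjusted p of 0.14. Lists of lysophosphatidic acid receptors and metabolism (adjusted p = 0.58) and of genes near Lpar4 (adjusted p = 0.72) were not called, and Lpar1 differed by -0.27 ± 0.07 (adjusted p = 0.12).

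Of the 54 lists camera called 23, 16 higher and 7 lower, and adjusted p among the other 31 ran from 0.078 to 0.95. The calls left to name are the T and NK cell list (higher, adjusted p = 0.029, and adjusted p = 0.29 with an estimated correlation), whose 18 members were all nearly constant, and the red blood cell list (higher, adjusted p = 0.032, and adjusted p = 0.28 with an estimated correlation), with 2 varying members. Of its 5 members 1 rose, Slc4a1 (0.50 ± 0.06), an anion exchanger of red cells named after its values were seen, while its globin genes were nearly constant. No call held with an estimated correlation, where the lowest adjusted p was 0.22 and 8 lists had an unadjusted p under 0.05, while fry called 20 lists, 17 of them among the 23. Besides the mesothelial, macrophage and dendritic cell lists, fry did not call complex IV (adjusted p = 0.15), ATP synthase (adjusted p = 0.054) and branched-chain amino acid breakdown (adjusted p = 0.053). Other splits of the 8 arrays into 4 and 4 gave up to 32 called lists. Over all genes quantile normalization kept 9 of the 23 calls, with 3 lists called higher and 14 lower in all, and median centring kept 6, with 0 called higher and 18 lower, so the balance of 16 against 7 turned. In the varying genes alone these scalings kept 19 and 20 of the 21 lists that could be tested there. Median, mean and test differed in sign in 10 lists, none of them called, among them immediate early genes (median 0.02, mean -0.09) and smooth muscle and pericytes (median 0.08, mean -0.01).

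Measures of RNA quality did not separate the groups, and 1 measure of array scale did before adjustment. The 3′ minus 5′ difference of the Gapdh control probe sets was 0.57 ± 0.02 log2 in LPA4-KO and 0.59 ± 0.03 in WT arrays (exact permutation p = 0.54), and that of Actb 1.27 ± 0.07 and 1.18 ± 0.04 (exact permutation p = 0.17). The interquartile range of all probe sets was lower in all LPA4-KO arrays, 1.39 ± 0.003 against 1.41 ± 0.01 (exact permutation p = 0.0286, adjusted p = 0.20 over the 7 measures). Over the varying genes, the first principal component held 43.9% of the variance and separated the groups. The second (18.1%) cut across them, with LPA4-KO replicate 4 (-0.52) and WT replicate 2 (-0.57) opposite LPA4-KO replicate 1 (0.28) and WT replicate 4 (0.49). The third (12.7%) mostly set WT replicate 1 apart. Correlations between arrays across these genes, which are not independent replicates, were 0.978 to 0.991 within LPA4-KO, 0.971 to 0.986 within WT and 0.949 to 0.976 between groups.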

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

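The comparison of smooth muscle with progenitor markers, the scaling test within the varying genes, the splits of the list counts in the varying genes, the RNA quality test and the tests on Lpar4 were chosen after the results they bear on had been seen.

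The counts of genes were far above those of all other splits of the arrays, and the counts of lists were not. With 35 splits, 1 split as large is the strongest result possible. The splits also cannot separate genotype from another difference between the 2 groups. Of the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many called genes: 239, against at most 1 in any other split. With the varying genes alone the real split gave 859 and the highest other 1, again with 1 split as large. For gene lists 2 of the 35 splits gave as many as the real 23, with 32 in the highest other split and a median of 8. In the varying genes 3 of the 35 gave as many as the real 20, with 24 in the highest other. For 8 of the 23 called lists no other split gave as small a p. These were respiratory complex I, complexes II and III, the tricarboxylic acid cycle, mitochondrial fatty acid oxidation, fatty acid synthesis, fibrillar collagen and matrix, basement membrane, and progenitors and fibroblasts. For the other called lists, 2 to 9 of the 35 splits gave as small a p, the real one included. Among them were complex IV (9), ATP synthase (5), mitochondrial import (4), the mitochondrial ribosome (3), mesothelial cells (5) and macrophages (4). The splits do not exclude chance for these lists.

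A first pattern is that mitochondrial lists were higher while matrix, progenitor, macrophage and mesothelial lists were lower in LPA4-KO fat. The smooth muscle and pericyte score moved 0.46 ± 0.06 log2 (SE) apart from the progenitor and fibroblast score (exact permutation p = 0.0286). These 2 sets of markers thus did not fall alike. The smooth muscle score changed by -0.01 ± 0.09, and by 0.12 ± 0.08 without Acta2, which moved against Actg2. The blood endothelial score changed by -0.14 ± 0.05 (exact permutation p = 0.0286, adjusted p = 0.057 over the scores compared). Marker levels may change within cells, so a loss of all cells other than adipocytes alike cannot be judged from these scores. A change in progenitor, macrophage or mesothelial cells alone also stays open. Scaling over all genes left 9 of the 23 list calls after quantile normalization, but the mean change of a called list moved by at most 0.028 log2, in cytosolic ribosomal proteins (-0.082 to -0.054), and by at most 0.017 in the others (complex I went from 0.19 ± 0.04 to 0.20), and the calls ended because a small common shift of nearly constant genes changed the genes that camera compares with. Within the varying genes 19 of 21 lists kept call and direction, which argues against scaling there. RNA quality stays open, with Actb 3′ minus 5′ higher by 0.090 and Gapdh by -0.012 log2, and so does the genotype, which no test here separates from a change in cell makeup.

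A second pattern is that the Lpar4 probe sets moved in opposite directions. A wrong genotype label on an array is argued against by 1452424_at, where the lowest WT array stood 0.63 log2 above the highest LPA4-KO array, with an SD within groups of 0.04. Whether RNA from the altered locus is still read by probe sets outside the deleted part could not be tested, since neither position was used here; the changes of the probe sets lay 1.39 log2 apart. Effects carried by the chromosome around the locus cannot be told apart from chance: 6 of the 20 measured genes nearest to Lpar4 in the GRCm38.p6 gene order had an unadjusted p under 0.05 (30.0%, against 17.6% of all genes; exact one-sided binomial p = 0.13), and 0 passed the adjusted threshold. The 6 were Magt1, Fndc3c1, Cysltr1, P2ry10, P2ry10b and Sh3bgrl, of which Cysltr1 differed by -0.30 ± 0.09 and P2ry10 by 0.37 ± 0.13, while Fndc3c1 (0.00043) and P2ry10b (-0.00040) were nearly constant.

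A further pattern is that 49 nearly constant genes were called, which may be a shrunken remainder of a real difference. Among all nearly constant genes with another probe set that varied, 420 of 617 (68.1%) went the same way as that probe set, but only 3 of the 49 had one, and 2 of these 3 went the same way, too few to decide.

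Single arrays stood apart from the other 3 of their group, by a gap whose share of the group's range exceeded Dixon's 95% critical value, in 13 of 264 groups tested, where chance gives about 13.2. Among the largest changes these were Ces1f in WT replicate 2 (ratio 0.833, highest) and Coasy in WT replicate 1 (0.887, highest). In mitochondrial and lipid genes they were Polrmt in WT replicate 2 (0.858, highest), Dld in WT replicate 4 (0.895, lowest), Bscl2 in WT replicate 3 (0.958, lowest), Dgat1 in LPA4-KO replicate 2 (0.835, lowest) and Pdk4 in WT replicate 2 (0.830, highest). The others were Ccl11 in LPA4-KO replicate 4 (0.859, lowest), Calr in WT replicate 2 (0.831, lowest), H2-Aa and H2-Eb1 in LPA4-KO replicate 1 (0.959 and 0.880, highest), Magt1 in WT replicate 1 (0.853, highest) and the Gapdh 3′ minus middle difference in WT replicate 1 (0.952, highest).

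Probe sets outside the gene comparison held signals too. Of 10092 probe sets without a single named gene, 13 were called (8 higher, 5 lower), 10 of them varying. The 4 array control probe sets of pyruvate carboxylase were higher in LPA4-KO arrays by 0.72 log2 on average (0.60 to 0.79), without overlap in any of the 4, beside 0.79 at the probe set of Pcx itself.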

How the results depend on the processing

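The fits restricted to varying genes were chosen after seeing the data, and the other alternatives were planned. The 44 called named genes kept their direction in all fits below. They kept their call in 303 of 352 planned results with all arrays, in 41 of 352 with 1 array left out and in all 176 restricted to varying genes. The 23 called lists kept call and direction in 186 of 251 planned results with all arrays, where 53 lost the call and 12 turned, in 172 of 184 with 1 array left out and in 59 of 84 restricted to varying genes.

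Against 239 called genes, 495 were called among genes above the median level, 361 with array weights, 882 at an adjusted p under 0.1 and 27 with a fold of at least 1.5. Quantile normalization gave 9436 and median centring 14910, because both shift nearly constant genes together. Leaving out 1 array gave from 9 to 88, with fewer samples. The varying genes alone gave 859, 878 with quantile normalization, 880 with median centring and 874 with the best varying probe set per gene. A robust fit (262), no trend (263), the plain equal-variance test (160), the mean of all probe sets per gene (236) and every probe set on its own (326) stayed within 1.5 times. The called genes were not all the same: the mean of all probe sets kept 185 of the 239. The 326 are probe sets, out of 34945 tested, and not genes. With an estimated correlation camera called 0 lists, with an unadjusted p under 0.05 in 8, and in the varying genes 0 lists, with 5, while fry called 20.

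Pairing of the arrays by replicate number was not evident, though 4 pairs are too few to exclude it. Deviations from the group means of arrays with the same number correlated at 0.02, 0.08, 0.24 and -0.18 across varying genes, and 2 of the 4 LPA4-KO arrays matched their own number best. With the replicate block limma called 0 genes (3096 at an unadjusted p under 0.05) over all genes, 747 in the varying genes and the same 23 lists, and Lpar4 at 1452424_at kept its fold change of -0.71 with an adjusted p of 0.085.

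The 2 scalings turned the direction of camera, which compares a list with nearly constant genes that shift together. The values here are of lists called in at least 1 of the fits, and lists called in neither turned as well, such as peroxisome, lipolysis, adipocyte identity and cholesterol synthesis. The mean log2 change of the varying members stayed positive in the lists given, except smooth muscle, which went from -0.012 to 0.0030 with centring. With quantile normalization these means were 0.11 for ATP synthase, 0.18 for the mitochondrial ribosome, 0.25 for triglyceride synthesis, 0.052 for lipid uptake, 0.066 for insulin signalling, 0.13 for endoplasmic reticulum stress and 0.15 for the proteasome. With median centring they were 0.17 for complex IV, 0.12 for ATP synthase, 0.17 for fatty acid oxidation, 0.25 for triglyceride synthesis, 0.045 for lipid uptake, 0.067 for insulin signalling, 0.17 for branched-chain amino acid breakdown, 0.13 for endoplasmic reticulum stress, 0.068 for antioxidant genes and 0.16 for the proteasome. Nearly constant genes also turned: Siglech to 0.0057 and 0.014 under these scalings and P2ry10b to 0.014 under centring.

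Lpar4 depended on the probe set, with -0.71 at 1452424_at against 0.48 at the probe set of highest mean. Quantile normalization put 1434186_at (0.69) past the threshold (adjusted p = 0.043). Against -0.012 for Gapdh 3′ minus 5′, LPA4-KO minus WT was 0.016 for Gapdh 3′ minus middle, 0.090 for Actb 3′ minus 5′ and 0.042 for Actb 3′ minus middle, and none passed its test. The cause of these differences between probe sets was not tested. An alternative for linear values did not apply to log values.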

Other observations

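The lists below were written after the called genes had been seen, and before their own values were. Single members are named after their values were seen. Each leaves out called genes and members of the fixed lists it grew from.

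A hypothesis from the falls of Klf10, Smad7 and matrix genes was that the response to transforming growth factor beta as a whole was lower. In a list of 36 other response genes 13 of 20 varying members were negative, with a median of -0.25 log2, and camera gave an adjusted p of 0.0012 over the 3 lists (adjusted p = 0.17 with an estimated correlation, adjusted p = 0.048 in the varying genes). In the varying genes alone 5 fell and 0 rose, among them Id3 (-0.51 ± 0.10), a target of bone morphogenetic protein signals as well, Ltbp3 (-0.42 ± 0.08), which encodes a binding protein of latent growth factor, and Cdh11 (-0.55 ± 0.15). The 7 positive members included Ccn2 (0.50 ± 0.33) and Ltbp2 (0.37 ± 0.22), against the direction and without passing. However, 3 of the 35 splits of the arrays gave as small a p, so chance is not excluded, and several members are also genes of fibroblasts, so the test does not separate a lower response from fewer such cells.

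Other chaperones and mitochondrial carriers were tested in the same way. For partners of HSP90 and cytosolic chaperones outside the heat shock list, 13 of 18 varying members were positive (median 0.13 log2), with an adjusted p of 0.049 and adjusted p = 0.35 with an estimated correlation. In the varying genes the list had an adjusted p of 0.048, and 2 members rose, Chordc1 (0.49 ± 0.10) and Hspa2 (0.34 ± 0.10). Cryab, a small heat shock protein gene, fell there against the direction (-0.66 ± 0.18). The 3 called members left out, Ahsa2, Stip1 and Cacybp, had risen. However, 15 of 35 splits gave as small a p, so no wider rise was shown. Mitochondrial carriers and coenzyme Q genes outside the other lists were positive in 17 of 21 varying members (median 0.18 log2, adjusted p = 0.040, and adjusted p = 0.17 with an estimated correlation), and 6 of 35 splits gave as small a p. In the varying genes alone 4 of these rose, such as Slc25a35 (0.56 ± 0.15) and Coq3 (0.27 ± 0.06), and 1 fell, Slc25a24 (-0.35 ± 0.11).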
